A study of Mus musculus with 9 samples.

How the data were processed

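Gene expression was measured by RNA sequencing in gonads dissected away from the mesonephros of C57BL/6 mouse fetuses at embryonic day 13.5. The 9 samples fell into 3 groups of 3. XX-WT samples were control ovaries and XY-WT samples were control testes, both from animals carrying the floxed Sox9 alleles. XY-KO samples were testes in which Cre recombinase under the AMH promoter, active in Sertoli cells, deleted Sox9. Per the labels, total RNA was column-purified, amplified with the SPIA method, which avoids ribosomal RNA, and sequenced as read pairs of 150 nt.

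The values used were 3 deposited tables of the authors, each a comparison of a pair of groups over the same 15300 genes. Each table gave the authors' log2 fold change and the authors' mean log2 expression on the log2 CPM scale (CPM, read counts scaled to a common library total). It also gave the authors' limma scores, which are the moderated t score and the log-odds score. Per the file headers, the remaining columns were the limma p-value and its Benjamini-Hochberg adjusted p-value. The submitters' notes name Trimmomatic 0.30, TopHat2 2.0.8, HTSeq 0.6.1p1, limma 3.24.0 and the GRCm38 genome, and do not say how replicates were weighted or which genes were filtered out. No per-sample values were used here, so the depth of each sample is unknown, no counting interval or detection floor was computed, and no sample could be left out or regrouped.

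The tables were checked before use. Recomputing the Benjamini-Hochberg adjustment matched the deposited adjusted p within a relative difference of 0.000769. The 3 log2 fold changes added up within 0.005 for every gene, and t gave the deposited p at 15.27 degrees of freedom in all 3 tables, as a single fit of the 3 groups would. Standard errors (SE) were taken as the log2 fold change divided by t, and 95% intervals from them at those degrees of freedom. Group levels were derived from the mean and the fold changes by assuming equal weight for the groups. Where the derived level of a group was below -3 in log2 CPM, the fold change depends on the offset the authors added before taking logs, and only the log2 value is given. Gene positions, biotypes, and the length and GC content of the longest transcript came from GENCODE M21 on GRCm38, found for 15192 genes.

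A gene was called changed at a limma adjusted p under 0.05, with no fold limit, in each of the 3 comparisons. The number of genes, their direction, and 20 gene lists were reported. The lists were fixed before the data were examined: Sertoli cell markers, ovarian somatic (pre-granulosa and WNT) genes, fetal Leydig genes, interstitial and hedgehog target genes, meiotic genes, oocyte genes, male germ cell genes, general germ cell genes, endothelial, erythroid, macrophage and mesonephric markers, SOX9 cartilage targets, basement membrane genes, splicing factors, cholesterol synthesis genes, cell cycle genes, retinoic acid pathway genes, immediate early and heat shock genes, and Y-linked genes. Each list was tested two-sided on the moderated t with cameraPR of limma 3.58.1 in R 4.3.3 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 60 tests. This test compares a list with all other genes. The named genes were set by a rule: Sox9, then the 10 largest rises and 10 largest falls among called genes at or above the median mean expression of 3.19 that have a standard gene name, then for each list the 3 members with the smallest adjusted p and the best member of the other direction. Other genes named in the text were chosen after their values were seen, except members listed by name in the fixed lists.

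The share of sex-biased genes that moved toward the XX-WT level in XY-KO and the overlap of called genes are given as counts. The planned exact interval and Fisher's exact test take genes or lists as independent, which the shared XY-WT samples break, so they are not given. Position was the ratio of the XY-KO change to the XX-WT change, both against XY-WT, over genes with an XX-WT change of at least 2-fold and an adjusted p under 0.05. Both changes share the XY-WT samples, so 100 draws with that shared error were simulated. They were set beside the share moving the same way at an unadjusted p under 0.05, the correlation, the covariance and the main median positions. The share among genes called in both comparisons and the positions of the lists had no simulated value. The trend of the fold change with GC content and length was fitted by robust regression on polynomials of degree 3 over genes at or above median expression and was subtracted from all genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.

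Counts were repeated at an adjusted p under 0.01, with a 2-fold limit, on genes at or above median expression, with the adjustment made over the 3 comparisons together, and with Bonferroni adjustment. The list tests were repeated at a preset correlation of 0.05, in the rank form, with log2 fold changes ranked in place of t, and over genes at or above median expression. Removal of the GC and length trend (also for the lists), centring on the median, and restriction to autosomes were added after the data were seen. Changes of known size were planted on values with the standard errors of the tables. For XY-KO against XY-WT, 57.8% of 2-fold and 89.6% of 4-fold planted changes were called, 16% of 1.5-fold ones were, and 4.48% of the calls were not planted. All 20 random lists of 20 genes shifted by 0.5 on the log2 scale were called, and 0 of 20 unshifted ones. Errors were drawn independently between genes, so these draws do not cover lists whose members vary together. An imposed GC slope of -0.2 was measured as -0.199 and was -0.000908 after removal.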

Results

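Gene expression was compared among fetal mouse gonads of 3 kinds at E13.5, the stage in days after conception, with 3 samples each. These were control testis (XY-WT), control ovary (XX-WT) and testis with Sox9 deleted in Sertoli cells by Cre (XY-KO). SOX9 is the transcription factor that drives Sertoli cell differentiation, and Sertoli cells are the supporting cells that organise the testis. The labels do not say whether a sample came from a single fetus or a pool, so the errors describe the spread between samples. All gene values below are the authors' own limma results for group against group, in log2 units with the standard error (SE) implied by the authors' t. The depth of each sample is unknown here. Coordinates are for GRCm38.

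The first comparison, XY-KO against XY-WT, asks which genes of the fetal testis depend on Sox9. Part of the Sertoli cell gene set was lower in XY-KO, together with collagen genes that SOX9 drives in cartilage, while none of the 12 measured fetal Leydig genes passed the test. Of 30 Sertoli cell markers, 15 fell and none rose, and Amh, the hormone that makes the Müllerian ducts regress, was 4.16-fold lower (95% interval 3.09 to 5.6). Among 18 genes of the ovarian somatic programme none rose. The authors' deposited table held 347 genes with an adjusted p under 0.05, 107 higher and 240 lower in XY-KO.

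Sox9 itself (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760) fell by 2.76 on the log2 scale in the authors' deposited table (SE 0.172, adjusted p 8.93e-07), to a level 6.78-fold lower than in XY-WT (95% interval 5.26 to 8.75). A whole-gene count cannot say which exons the remaining reads came from, nor whether every Sertoli cell had lost the gene. The labels of sex chromosome content held: Xist, the RNA of the inactive X, differed by 0.04 between XY-KO and XY-WT (adjusted p 0.959), and none of 5 Y-linked genes was called.

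Sertoli cell markers had a median log2 fold change of -0.94, and the list was lower than other genes (adjusted p 1.30e-35). Adjusted over the list alone, 23 of the 30 fell and 1 rose. The authors' deposited table put the largest falls of the list at -3.93 (SE 0.477) for Sox10, a SOX9 relative, -2.62 (SE 0.288) for Cldn11, a tight junction protein of Sertoli cells, and -2.53 (SE 0.289) for Tesc. Col9a3 (chromosome 2, 180597790 to 180622189) fell by 2.17 (SE 0.151, adjusted p 2.02e-06) and Amh (chromosome 10, 80805243 to 80807648) fell by 2.06 (SE 0.202, adjusted p 5.42e-05). In the same deposited table of the authors, Ptgds, the prostaglandin D synthase that acts with SOX9, stood at -1.51, the secreted signals Dhh and Gdnf both at -1.34, Mmd2 at -1.34, Shbg at -1.33, Cbln4 at -1.16, Aard at -1.14, Cst9 at -1.12, Cst8 at -0.76 and Nedd9 at -0.69, each past the test. Other markers did not pass: the authors' deposited table gave Sox8, a close relative of Sox9, -0.70 (adjusted p 0.0888), the retinoic acid degrading enzyme Cyp26b1 -0.27 (adjusted p 0.262), Inhbb -0.15, Hsd17b3, an enzyme of testosterone synthesis, 0.13 (adjusted p 0.777), and Wt1 0.44 (adjusted p 0.139). The trend with GC content and length described with the last comparison had a median of -0.16 over this list, and 14 of its genes were lower with that trend removed.

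**Figure D1:**
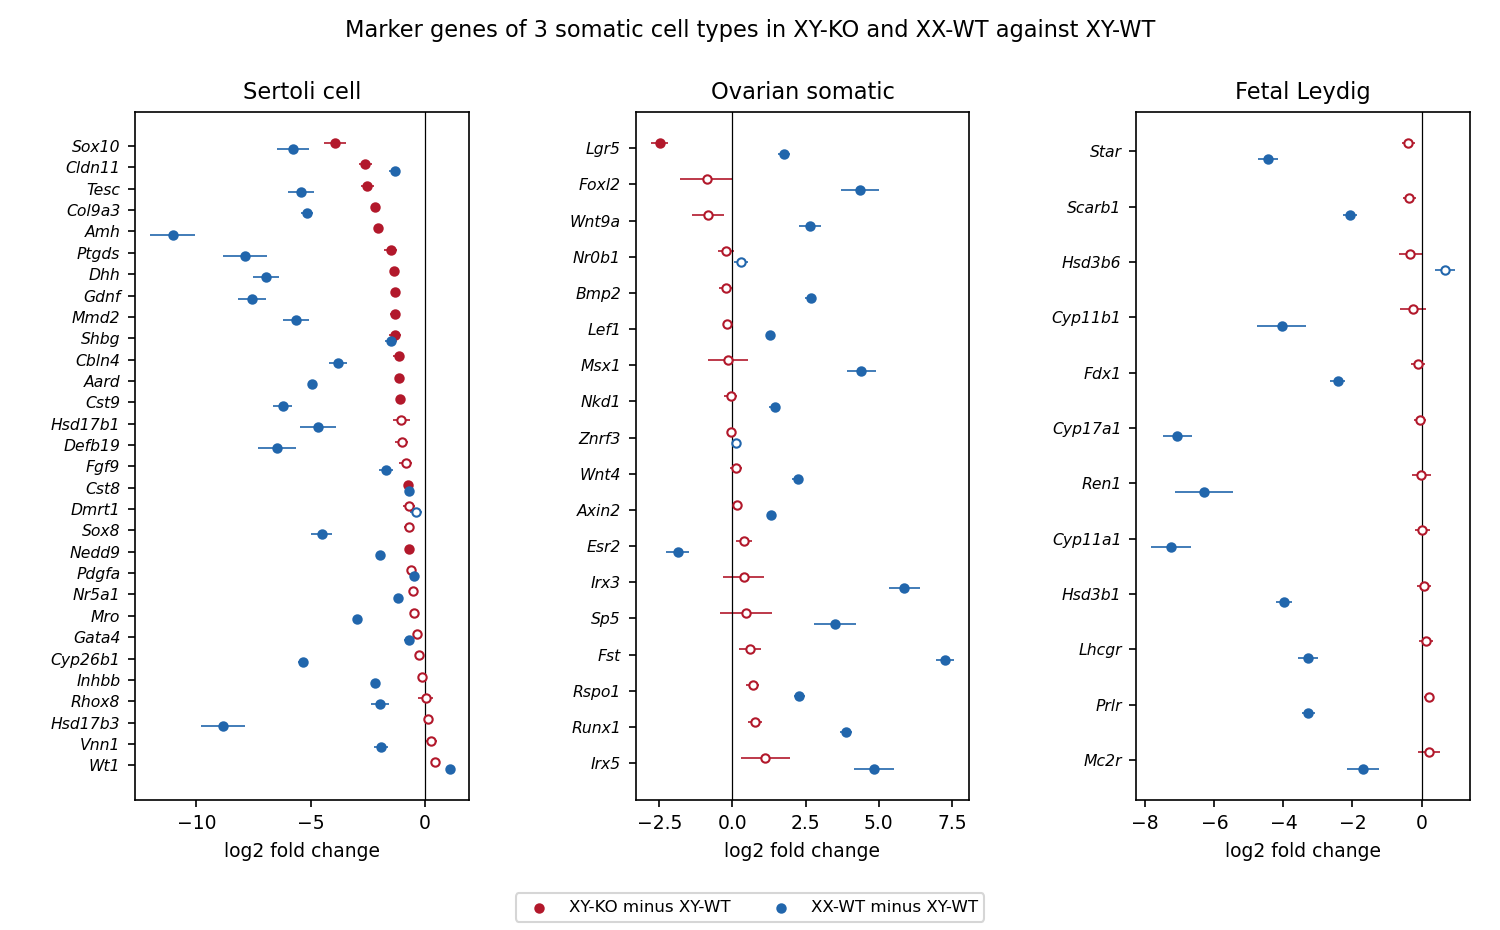
Log2 fold change of each measured Sertoli cell, ovarian somatic and fetal Leydig gene in XY-KO (red) and XX-WT (blue) against XY-WT; bars are the SE implied by the authors' tables, and filled points have an adjusted p under 0.05. Of 30 Sertoli cell genes 15 fell in XY-KO, against 28 in XX-WT, and no Leydig gene was called in XY-KO.

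SOX9 cartilage targets moved as a list (adjusted p 2.46e-07), with 4 of 9 measured members lower and none higher; adjusted over the list alone, 4 fell and 1 rose. All 4 are fibrillar or associated cartilage collagens: the authors' deposited table gave Col9a3 as above, Col9a1 -2.13 (SE 0.294), Col9a2 -1.88 (SE 0.250) and Col2a1 -1.35 (SE 0.231). The other 5 members did not pass, among them Sox5 (0.41, adjusted p 0.198) in the authors' deposited table. The list's median was -0.06 against a mean of -0.75 (median -0.14 with the trend removed), and with ranks in place of t its adjusted p was 0.348.

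Of the interstitial and hedgehog target genes, 2 of 12 fell and 1 rose (adjusted over the list alone, 3 fell and 1 rose), with a median of -0.22. The authors' deposited table gave Hhip, a hedgehog-binding target of the pathway, -1.26 (SE 0.135, adjusted p 9.06e-05), the hedgehog receptor Ptch1 -0.61 (adjusted p 0.0147) and the transcription factor Maf 0.50 (adjusted p 0.0344). Removing the GC and length trend took Maf to an adjusted p of 0.0543. The list's adjusted p was 0.00479, a call that ended in the rank form of the test (0.0529) and with fold changes ranked in place of t (0.0958). With the trend removed it was 0.00777, while the median was -0.01 and 2 genes were lower. Basement membrane genes had 1 of 11 lower, Col18a1 (-1.08, adjusted p 0.00207) in the authors' deposited table, and 2 adjusted over the list alone (list adjusted p 0.121).

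Fetal Leydig genes had a median of -0.03 and an adjusted p of 0.803, with 0 of 12 called by limma, also when adjusted over the list alone, and 0 at an unadjusted p under 0.05. The authors' deposited table placed Star, which carries cholesterol into mitochondria, at -0.38 (adjusted p 0.294), Cyp11a1, which makes the first steroid, at 0.02 (adjusted p 0.974) and Cyp17a1 at -0.05 (adjusted p 0.909). Cholesterol synthesis genes had 0 of 18 called (1 fell when adjusted over the list alone, and 1 had an unadjusted p under 0.05; list adjusted p 0.345). Among ovarian somatic genes 1 of 18 fell and none rose; adjusted over the list alone, 2 rose and 1 fell, and the list's adjusted p was 0.970. The gene that fell was Lgr5 (chromosome 10, 115450311 to 115587780), a receptor for R-spondins, at -2.49 (SE 0.30, adjusted p 0.000276) in the authors' deposited table. Runx1 (0.77, adjusted p 0.0981) and Rspo1 (0.69, adjusted p 0.103) did not pass in the authors' deposited table, and Rspo1 passed once the GC and length trend was removed (adjusted p 0.0156).

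Germ cell genes gave few calls. None of 15 meiotic genes (list adjusted p 0.383), 3 oocyte genes (0.781 for the list) or 11 male germ cell genes (0.135 for the list, or 0.0253 with fold changes ranked) was called by limma, and none when adjusted over each list alone. At an unadjusted p under 0.05 there were 0, 0 and 2 of them. General germ cell genes were lower as a list (median -0.38, adjusted p 0.0124; -0.23 and 0.0193 with the GC and length trend removed), with 1 of 12 called, also over the list alone. That gene was the pluripotency factor Utf1, at -1.15 in the authors' deposited table (adjusted p 0.0277); with the GC and length trend removed its change was -0.64 and its adjusted p 0.250, as part of the fall lay in the trend. Cell cycle genes were lower as a list (median -0.33, adjusted p 8.82e-07), with 1 of 17 called and 10 when adjusted over the list alone. The called gene, the replication licensing factor Mcm2, stood at -0.66 (adjusted p 0.0469) in the authors' deposited table and at an adjusted p of 0.115 with the trend removed.

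None of the other lists had a member called by limma in this comparison. For the other cell types a gonad holds, list adjusted p was 0.383 for 15 endothelial, 0.287 for 12 erythroid, 0.885 for 10 macrophage and 0.345 for 5 mesonephric markers (0.00839 for the last with fold changes ranked), with 3, 3, 0 and 1 members at an unadjusted p under 0.05. Adjusted over the list alone, 1 of these markers fell, the receptor Ret, at -2.47 in the authors' deposited table (SE 0.696). For 34 splicing factors, the list to which the study's interest in splicing points, the median was 0.04 and the adjusted p 0.402, with 5 at an unadjusted p under 0.05 and 0 called when adjusted over the list alone; the smallest gene-level adjusted p in the authors' deposited table belonged to Tia1 (0.44, adjusted p 0.109). Retinoic acid pathway genes had a list adjusted p of 0.643, with 1 of 8 at an unadjusted p under 0.05 and 0 called when adjusted over the list alone. Immediate early and heat shock genes, which respond to handling of tissue, had a median of -0.40 (adjusted p 0.0775, or 0.0486 with fold changes ranked; 3 had an unadjusted p under 0.05 and fell when adjusted over the list alone), and with the GC and length trend removed the median was -0.11. Y-linked genes had a median of 0.36 (adjusted p 0.0198; 3 had an unadjusted p under 0.05 and rose when adjusted over the list alone), and this call ended with fold changes ranked (adjusted p 0.264) and with the trend removed (adjusted p 0.285), where the median was 0.25.

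Among called genes at or above median expression with a standard gene name, the authors' deposited table showed the largest falls after Sox9, Lgr5 and Col9a3 for Trank1 (-1.95), the protease inhibitor Serpine2 (-1.94, SE 0.142, adjusted p 2.93e-06), Sel1l3 (-1.79), the dystrobrevin gene Dtna (-1.59), AU015836 (-1.55), the glutathione transferase Gstm7 (-1.48) and the potassium channel Kcnh1 (-1.41). Within the same limit the authors' deposited table showed the largest rises for the perinatal myosin heavy chain Myh8 (1.66, SE 0.248, adjusted p 0.00148), the steroid-metabolising aldo-keto reductase Akr1c14 (1.45), the collagen Col6a6 (1.45), Gxylt2 (1.44), the calcium channel Cacna1d (1.33), Mllt3 (1.20), Podxl (1.20), the tight junction gene Cgn (1.18), Daam2 (1.17) and the desmosomal cadherin Dsc2 (1.15). At least 2-fold changes were called for 61 higher and 129 lower genes. With the GC and length trend removed, 116 genes were higher and 142 lower, of which 79 and 134 had been called in the same direction before. On planted data 57.8% of 2-fold changes were called, so a gene not called here may still differ by that much.

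The second comparison, XX-WT against XY-WT, measures the sex difference of the control gonads, against which the knockout is read. Ovaries had low levels of Sertoli and Leydig genes and high levels of ovarian somatic and meiotic genes. Cyp11a1 was 152-fold lower (95% interval 65.1 to 355) and Fst, an activin-binding protein, was 154-fold higher (95% interval 98.5 to 242) in XX-WT. The authors' deposited table held 3560 genes with an adjusted p under 0.05, 1661 higher and 1899 lower in XX-WT, of which 876 and 960 changed at least 2-fold. Sox9 was at -4.47 there (SE 0.216, adjusted p 2.06e-09), 22.2-fold lower.

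Of the 30 Sertoli cell markers 28 were lower and 1 higher, with the same counts when adjusted over the list alone (list adjusted p 2.65e-45). The authors' deposited table gave Aard -4.93 (adjusted p 3.92e-10), Cyp26b1 -5.34 (adjusted p 3.92e-10), Col9a3 -5.17 and Amh -11.04, the last against an XX-WT level near the floor, and Wt1 1.09 in the other direction. Fetal Leydig genes had 11 of 12 lower and none higher (adjusted over the list alone, 11 lower and 1 higher; list adjusted p 1.10e-26). The authors' deposited table placed Cyp17a1 at -7.07, the progesterone-making Hsd3b1 at -3.99, Prlr at -3.27 and Hsd3b6 at 0.68 (adjusted p 0.102); reads may be shared between the related Hsd3b1 and Hsd3b6. Interstitial and hedgehog genes had 10 of 12 lower (11 adjusted over the list alone; list adjusted p 2.30e-18), with Hhip -5.13, Ptch1 -2.43 and the smooth muscle actin Acta2 -2.08 in the authors' deposited table. Cholesterol synthesis genes had 13 of 18 lower (15 adjusted over the list alone; list adjusted p 4.56e-07), among them Msmo1 (-1.23), Lss (-1.20) and Fdps (-1.21) in the authors' deposited table. SOX9 cartilage targets had 7 of 9 lower and 1 higher (the same over the list alone; list adjusted p 7.40e-07), with Col2a1 -2.30, Col9a2 -1.89 and Sox5 0.59 in the authors' deposited table. Basement membrane genes had 6 of 11 lower, also over the list alone (list adjusted p 5.25e-05, a call that ended with fold changes ranked, 0.0628), among them Col4a1 (-1.92) and Col4a2 (-1.62) in the authors' deposited table; the GC and length trend had a median of -0.22 over them, and 5 were lower with it removed.

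Ovarian somatic genes had 15 of 18 higher and 1 lower, also over the list alone (list adjusted p 1.33e-27). The authors' deposited table gave Fst 7.27 (SE 0.305), Runx1 3.89 (SE 0.207), Bmp2 2.67 (SE 0.183) and the WNT co-activator Rspo1 2.28, with the oestrogen receptor Esr2 at -1.87. Meiotic genes had 10 of 15 higher (11 adjusted over the list alone; list adjusted p 1.0e-08); the authors' deposited table gave the meiotic cohesins Rec8 3.72 and Smc1b 2.10, the chromosome axis gene Hormad1 1.48, and Msh5 -0.16 (adjusted p 0.805). General germ cell genes had 6 of 12 higher (8 adjusted over the list alone; list adjusted p 0.00942, a call that ended over genes at or above median expression, 0.0602, and with fold changes ranked, 0.0508), with Tfap2c 1.81, Sox2 1.22 and Sall4 1.03 in the authors' deposited table. Male germ cell genes went both ways, 4 higher and 4 lower of 11 (adjusted over the list alone, 6 and 4): the nodal pathway genes Lefty2 (-7.03), Tdgf1 (-5.50) and Lefty1 (-5.49) were lower and the piRNA pathway gene Mael (1.43) was higher in the authors' deposited table. That list's median was 0.71 while its mean was -1.23 and its test pointed down (adjusted p 0.833, or 0.000171 with fold changes ranked). Retinoic acid pathway genes had 2 higher and 2 lower of 8 (adjusted over the list alone, 5 and 2), with Cyp26b1 and Aldh1a1 (-2.75) lower and Crabp1 (2.24) higher in the authors' deposited table. Their median was 0.63 while the test pointed down (adjusted p 0.0265). This call ended at a preset correlation of 0.05 (adjusted p 0.0530) and with fold changes ranked (adjusted p 0.583), and turned upward in the rank form (adjusted p 0.260).

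Mesonephric markers had 4 of 5 higher and 1 lower, also over the list alone (list adjusted p 0.128, or 0.00211 with fold changes ranked in place of t), with Ret 2.35, Pax8 2.09 and Lhx1 -1.91 in the authors' deposited table. Endothelial markers had 1 higher and 4 lower of 15, also over the list alone (list adjusted p 0.287); the authors' deposited table gave Pecam1 0.39, Cdh5 -0.60 and Sox7 -0.61, and Sox7 did not pass with the GC and length trend removed (adjusted p 0.0548). Erythroid markers had 1 of 12 higher (0 adjusted over the list alone; list adjusted p 0.368), the embryonic globin Hbb-bh1 at 1.24 in the authors' deposited table. Macrophage markers had 1 of 10 higher, also over the list alone (list adjusted p 0.339), Adgre1 at 1.05 in the authors' deposited table. Immediate early and heat shock genes had 5 of 9 lower, also over the list alone (list adjusted p 0.00267, a call that ended over genes at or above median expression, 0.136), among them Hspa1b (-3.29), Hspa1a (-2.53) and Nr4a1 (-2.38) in the authors' deposited table; the first 2 are near-identical copies. Cell cycle genes had 5 of 17 lower, also over the list alone (list adjusted p 0.162, or 0.0437 in the rank form), among them Aurkb (-0.80) in the authors' deposited table. Splicing factors had 2 higher and 2 lower of 34, also over the list alone (list adjusted p 0.811), with Khdrbs3 0.76, Mbnl2 -0.39 and Khdrbs1 -0.45 in the authors' deposited table. Oocyte genes had Ybx2 higher (1.08) and Ooep lower (-1.0) of 3 measured, also over the list alone (list adjusted p 0.643), again in the authors' deposited table. All 5 Y-linked genes were lower, also over the list alone (list adjusted p 1.19e-22) and Xist was at 9.62 (SE 0.240) in the authors' deposited table, the directions the labels give.

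Outside the lists and among genes at or above median expression, the authors' deposited table put the largest rises in XX-WT after Xist at Gxylt2 (3.92), Adamts19 (3.89), Tnfrsf19 (3.73), Lrrn1 (3.58), Col12a1 (3.26), Egfl6 (3.21), Sorbs2 (3.06) and the calcium release channel Ryr2 (2.92). The largest falls among them in the authors' deposited table, besides genes given already and the Y-linked Uty (-5.65) and Kdm5d (-5.48), were Prokr2 (-6.33) and the alcohol dehydrogenase Adh1 (-5.61).

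The third comparison, XY-KO against XX-WT, asks how far the knockout testis stood from an ovary. XY-KO had high levels of steroidogenic genes and of most Sertoli cell markers relative to XX-WT, and low levels of ovarian somatic and meiotic genes. Cyp17a1 was 130-fold higher (95% interval 70.2 to 241) and Fst 102-fold lower (95% interval 70.3 to 149) in XY-KO. The authors' deposited table held 2796 genes with an adjusted p under 0.05, 1402 higher and 1394 lower in XY-KO, of which 803 and 737 changed at least 2-fold. Sox9 was at 1.71 there (SE 0.235, adjusted p 8.14e-05), 3.28-fold higher than in XX-WT.

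Sertoli cell markers had 21 of 30 higher and 2 lower (adjusted over the list alone, 23 and 2; list adjusted p 1.48e-27). The authors' deposited table gave Cyp26b1 5.07 (SE 0.214), Aard 3.79, Mro 2.52 and, in the other direction, Wt1 -0.65 and Cldn11 -1.29. Fetal Leydig genes had 11 of 12 higher and 1 lower, also over the list alone (list adjusted p 4.89e-31); the authors' deposited table gave Cyp11a1 7.27, Hsd3b1 4.06, Star 4.07, Prlr 3.49 and Hsd3b6 -1.01. Interstitial and hedgehog genes had 9 of 12 higher (10 adjusted over the list alone; list adjusted p 1.70e-16), with Hhip 3.87, Acta2 1.88 and Ptch1 1.82 in the authors' deposited table. Cholesterol synthesis genes had 12 of 18 higher (adjusted over the list alone, 13 higher and 1 lower; list adjusted p 8.82e-07), with Lss 1.39, Msmo1 1.32 and Cyp51 1.15 in the authors' deposited table. SOX9 cartilage targets had 5 of 9 higher, also over the list alone (list adjusted p 0.00512, a call that ended in the rank form, 0.0795), with Col9a3 3.0, Sox6 1.14 and Hapln1 0.79 in the authors' deposited table. Basement membrane genes had 5 of 11 higher, also over the list alone, with a median of 0.06 (list adjusted p 0.000979, a call that ended in the rank form, 0.120, and with fold changes ranked, 0.181), with Col4a1 1.65, Col4a2 1.31 and Nid1 1.24 in the authors' deposited table.

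Ovarian somatic genes had 15 of 18 lower and 1 higher, also over the list alone (list adjusted p 1.53e-35). The authors' deposited table gave Fst -6.68, Runx1 -3.11, Bmp2 -2.90 and Lgr5 -4.25, with Esr2 at 2.25. Meiotic genes had 9 of 15 lower (10 adjusted over the list alone; list adjusted p 5.79e-09), among them Rec8 (-3.11), Smc1b (-2.20) and Hormad1 (-1.75) in the authors' deposited table. General germ cell genes had 8 of 12 lower (10 adjusted over the list alone; list adjusted p 5.52e-06), among them Tfap2c (-2.40), Sox2 (-1.83) and Sall4 (-1.57) in the authors' deposited table. Male germ cell genes had 4 higher and 4 lower of 11 (adjusted over the list alone, 4 and 6; list adjusted p 0.643), with Lefty2 6.93, Tdgf1 4.97 and Piwil2 -1.60 in the authors' deposited table; the median was -0.82, the mean 0.84 and the test pointed down, and with fold changes ranked the adjusted p was 0.00686. Retinoic acid pathway genes had 2 higher and 2 lower of 8, also over the list alone (median -0.34, test upward, adjusted p 0.00512), a call that ended with fold changes ranked (adjusted p 0.317) and turned downward in the rank form (adjusted p 0.326); Aldh1a1 was at 2.88 and Crabp1 at -1.87 in the authors' deposited table.

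Erythroid markers had 5 of 12 lower, also over the list alone (list adjusted p 0.0859, or 0.0293 in the rank form). Among them were Hbb-bh1 (-1.53), Hba-x (-1.15) and Hba-a2 (-0.93) in the authors' deposited table. With the GC and length trend removed 1 was lower, while the list median was -0.42 against -0.50 before. Hba-x and Hba-a2 then had an adjusted p of 0.0513 and 0.0531. Mesonephric markers had 4 of 5 lower and 1 higher, also over the list alone (list adjusted p 0.0333, or 0.0530 at a preset correlation of 0.05 and 0.0684 in the rank form), with Ret -4.82, Gata3 -2.22 and Lhx1 1.44 in the authors' deposited table. Immediate early and heat shock genes had 4 of 9 higher (5 adjusted over the list alone; list adjusted p 0.0224, or 0.0521 at a preset correlation of 0.05, 0.146 in the rank form and 0.288 over genes at or above median expression), with Hspa1b 2.89, Hspa1a 2.42 and Egr1 1.26 in the authors' deposited table. Endothelial markers had 1 higher and 1 lower of 15 (2 and 1 over the list alone; list adjusted p 0.50), Tek at 0.87 and Pecam1 at -0.48 in the authors' deposited table. Macrophage markers had 1 of 10 lower (0 adjusted over the list alone; list adjusted p 0.326), Adgre1 at -0.96 in the authors' deposited table. Cell cycle genes had 2 of 17 lower, also over the list alone (list adjusted p 0.287), Mcm6 (-0.55) and Mcm3 (-0.44) in the authors' deposited table. Splicing factors had 1 higher and 1 lower of 34, also over the list alone (list adjusted p 0.833), Mbnl1 at 0.40 and Khdrbs3, a relative of Sam68, at -1.13 in the authors' deposited table. Oocyte genes had Ooep higher (1.0) and Ybx2 lower (-1.17) of 3 measured (adjusted over the list alone, 1 higher and 2 lower; list adjusted p 0.468) in the authors' deposited table. All 5 Y-linked genes were higher, also over the list alone (list adjusted p 2.57e-30) and Xist was at -9.58 in the authors' deposited table.

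Among genes at or above median expression, the authors' deposited table also put Prokr2 (6.03), Adh1 (5.38) and the activin subunit Inhba (4.06) among the largest rises in XY-KO. Tnfrsf19 (-3.94), Col12a1 (-3.19), Adamts19 (-3.12), Bhlhe41 (-3.01), Nr6a1 (-2.92) and the phosphatase Dusp9 (-2.92) were among their largest falls in the authors' deposited table. Over the 3 comparisons 31 of the 60 list tests passed, and 28 did at a preset correlation of 0.05. A correlation estimated from the data could not be had without per-sample values.

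**Figure D2:**
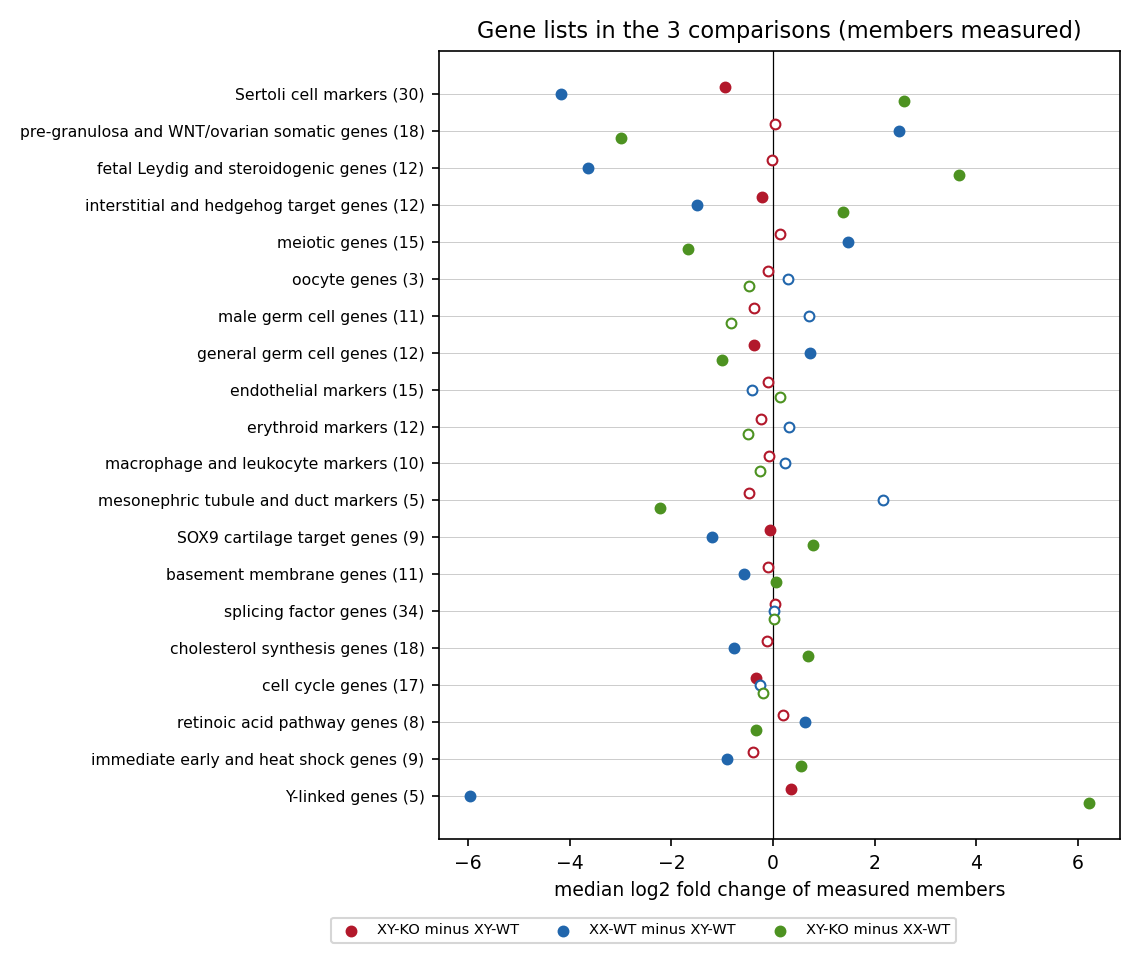
Median log2 fold change of the measured members of each of the 20 gene lists in the 3 comparisons; filled points have a list adjusted p under 0.05. Sertoli cell markers lay at -0.94 in XY-KO and at -4.16 in XX-WT against XY-WT, and fetal Leydig genes at -0.03 and -3.64.

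Whether Sox9 loss moved sex-biased genes toward the ovary was read from genes called in both comparisons with XY-WT. Of 266 such genes, 257 moved toward the XX-WT level in XY-KO (96.6%). These were 205 genes lower in both groups and 52 higher in both. A further 7 genes were higher in XY-KO and lower in XX-WT, and 2 were lower in XY-KO and higher in XX-WT, Lgr5 among the 2. Of the 240 genes that fell in XY-KO, 123 moved toward XX-WT and were not called against XX-WT, 77 were still called on the XY-WT side, 5 went beyond XX-WT and 33 were not sex-biased. Of the 107 that rose, the same counts were 30, 21, 1 and 48.

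Both changes share the XY-WT samples, whose error moves them alike. Of 1631 genes with an unadjusted p under 0.05 in both, 91.2% moved the same way, against 99.95% simulated with neither group changed and 78.5% with only XY-KO unchanged, so this share alone does not separate a response from shared error. The correlation of the 2 log2 fold changes across genes was 0.436, against 0.532 simulated with neither group changed and 0.157 with only XY-KO unchanged; genes are not independent replicates. The covariance, 0.208, exceeded the simulated shared error of 0.0463. Among genes chosen instead on XY-KO against XX-WT, XY-KO lay between the 2 controls for 1213 of 2796 (43.4%), against 37.6 to 41.7% simulated with XY-KO unchanged.

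**Figure D3:**
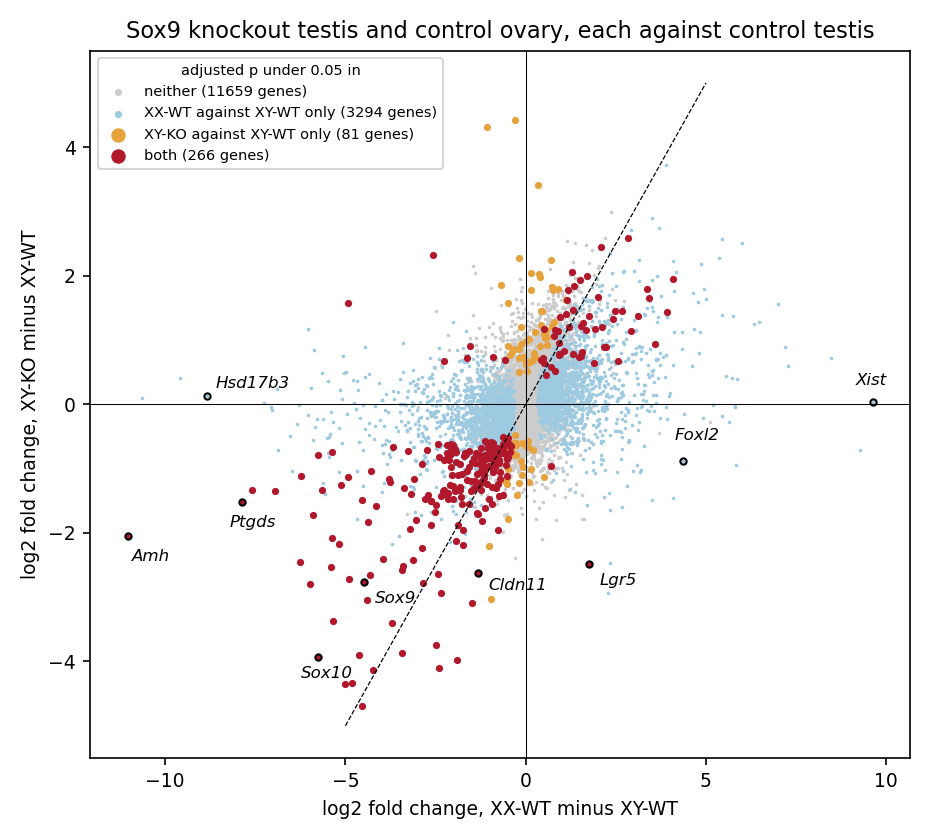
Log2 fold change of each gene in XY-KO (vertical) against that in XX-WT (horizontal), both relative to XY-WT, with genes coloured by the test they passed and the dashed line marking equal changes. Of 266 genes called in both, 257 moved the same way; Lgr5 moved apart, and Hsd17b3 lay near 0 in XY-KO.

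On the scale from 0 at XY-WT to 1 at XX-WT, the median position of XY-KO over 1836 sex-biased genes was 0.186 (quartiles -0.00919 to 0.428), against 0.0364 simulated with XY-KO unchanged. Over the 1540 genes called with a change of at least 2-fold in XY-KO against XX-WT, a choice made after the data were seen, it was -0.0263, within the range simulated with XY-KO unchanged (mean -0.0338, highest -0.0236). Testis-biased genes (960) stood at a median of 0.184 and ovary-biased genes (876) at 0.192, against 0.0208 and 0.0638 simulated with XY-KO unchanged. With the GC and length trend removed these medians were 0.118 and 0.211. Over genes at or above median expression they were 0.153 and 0.115, or 0.0751 and 0.117 with the trend removed. No test of a difference between lists was run. By list, testis-biased SOX9 cartilage targets lay at 0.587 (5 genes), Sertoli cell markers at 0.193 (25), basement membrane genes at 0.165 (4), interstitial and hedgehog genes at 0.127 (7), male germ cell genes at 0.0860 (4), immediate early and heat shock genes at 0.0839 (4), cholesterol synthesis genes at 0.0225 (7), fetal Leydig genes at 0.000874 (11) and Y-linked genes at -0.0428 (5). With the GC and length trend removed, basement membrane genes stood at 0.0272, interstitial and hedgehog genes at 0.0450, male germ cell genes at 0.0374, immediate early and heat shock genes at -0.0237 and cholesterol synthesis genes at -0.0694. Ovary-biased ovarian somatic genes lay at 0.0557 (15 genes) and meiotic genes at 0.0119 (10). Both lay below the 0.0638 simulated for all ovary-biased genes with XY-KO unchanged. With the GC and length trend removed they stood at 0.0811 and 0.0107, the first above that value. No list had a simulated value of its own. Ovary-biased mesonephric markers had a median of -0.260 (4 genes, 50% above 0), male germ cell genes -0.388 (4 genes, 25% above 0) and general germ cell genes -0.502 (3 genes, 0% above 0), and limma called none of these 11 genes in XY-KO against XY-WT. With the trend removed these 3 were at -0.121, -0.355 and -0.359. Upper-half expression genes had a median of 0.146, or 0.0874 with the GC and length trend removed, so the size of the shift depends on the genes taken.

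Fold changes against XY-WT also varied with the GC content of the transcript. Over 7622 genes at or above median expression, the slope per 10 percentage points of GC was -0.189 (SE 0.00525) in XY-KO against XY-WT, -0.187 (SE 0.0120) in XX-WT against XY-WT and -0.00148 (SE 0.0111) in XY-KO against XX-WT. In the eighth of genes lowest in GC the median change in XY-KO was 0.12, and in the eighth highest in GC it was -0.27. Spearman correlations with transcript length across genes were 0.225 in XY-KO and 0.0662 in XX-WT against XY-WT. The SEs of the GC slopes are over genes and do not measure the spread between libraries. Both comparisons with XY-WT share its samples, so their slopes are not independent. The labels name no batch, so library preparation and group cannot be separated for this trend.

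**Figure D4:**
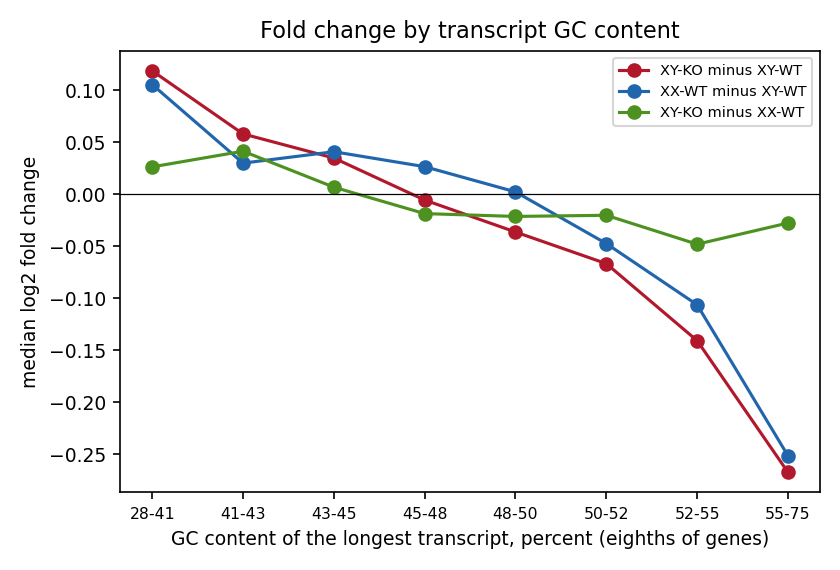
Median log2 fold change by eighth of transcript GC content (percent) for genes at or above median expression, in the 3 comparisons. Both comparisons with XY-WT fall from 0.12 and 0.11 in the lowest eighth to -0.27 and -0.25 in the highest, while XY-KO against XX-WT stays between -0.05 and 0.04.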

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

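The tests with removal of the GC and length trend, centring, autosomes alone and the slope over all genes were chosen after the data were seen; the others were fixed before. No paired analysis was possible because the tables hold no per-sample values and replicate numbers pair no samples. For the same reason leaving out replicates, a replicate block, another pseudocount, other size factors, another count filter, other count models and other splits of the samples were not run, and the depth that limits the weakest genes is unknown.

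Counts in the order XY-KO against XY-WT, XX-WT against XY-WT and XY-KO against XX-WT were 139, 2127 and 1699 at an adjusted p under 0.01, 190, 1836 and 1540 with a 2-fold limit, 206, 1879 and 1397 over the 7651 genes at or above median expression, and 55, 627 and 481 with Bonferroni adjustment, each stricter or over fewer genes by construction. Adjustment over the 3 comparisons together gave 922 genes for XY-KO against XY-WT, since the many small p-values of the other tables then relax its threshold, and 3129 and 2680 for the others. Trend removal gave 258, 3398 and 2803, centring 364, 3569 and 2817, and autosomes alone 308, 3309 and 2574. More genes fell than rose in XY-KO against XY-WT under all of these settings.

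The share of sex-biased genes moving toward XX-WT was 99.1% at an adjusted p under 0.01 and 97.7% with a 2-fold limit. It was 95.5% at or above median expression and 95.9% with the trend removed. A different measure was the share of the 2796 genes called in XY-KO against XX-WT for which XY-KO lay between the controls. This was 43.4%, against a mean of 39.7% simulated with XY-KO unchanged. That choice by construction favours genes where XY-KO and XX-WT differ. The median position was 0.238 with no fold limit, 0.150 with a 4-fold limit, 0.146 at or above median expression and 0.152 with the trend removed; the cause was not tested. The slope through 0 was 0.182, and that over all genes corrected for sampling error was 0.198 (jackknife SE 0.0131 over chromosomes, not libraries).

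Of the list tests, the retinoic acid pathway reversed in the rank form, in XX-WT against XY-WT (adjusted p 0.260) and in XY-KO against XX-WT (adjusted p 0.326); the cause was not tested. Passing lists numbered 28 at a preset correlation of 0.05, 30 with fold changes ranked (7 lost and 6 gained), 25 in the rank form and 30 with the trend removed, against 31; over genes at or above median expression 3 calls were lost and 48 tests kept their side. Of the 252 named gene results, 241 kept their side of the threshold with the trend removed, 7 no longer passed and 4 newly passed, all in the same direction.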

Other observations

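The genes in the next 2 paragraphs were chosen after their values were seen. XY-KO also held genes called outside the range of both controls, 22 lower and 46 higher than in XY-WT and in XX-WT alike. Both comparisons share the XY-KO samples, whose error moves a gene the same way in both. No simulated value was set beside these counts. In the authors' deposited tables the tight junction gene Cldn11 was at -2.62 against XY-WT and -1.29 against XX-WT, Lgr5 at -2.49 and -4.25, Trank1 at -1.95 and -1.19, and the calcium sensor Stim1 at -1.21 and -1.29. Higher than both in the authors' deposited tables were the metallothionein Mt1 (1.78 and 1.02), the collagen Col6a6 (1.45 and 1.04), Daam2 (1.17 and 0.64), Fras1 (0.99 and 0.97) and the pro-apoptotic gene Bcl2l11 (0.72 and 0.92). With the GC and length trend removed, 14 genes were lower and 44 higher than in both controls.

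The muscle myosin genes Myh8 (1.66) and Myl1 (2.59, adjusted p 0.00607) rose in XY-KO and stood at 2.02 and 2.84 in XX-WT against XY-WT in the authors' deposited tables, while Myh3 (2.90, adjusted p 0.134) and Ttn (1.58, adjusted p 0.153) did not pass in XY-KO. On the X chromosome, 128 of 590 tested genes were higher and 75 lower in XX-WT against XY-WT, and 12 were higher and 12 lower in XY-KO against XY-WT. By gene type, the median change in XY-KO against XY-WT was 0.95 for 38 sense intronic RNAs, 0.93 for 15 snRNAs, 0.72 for 31 misc RNAs, 0.63 for 197 processed pseudogenes, 0.36 for 361 lincRNAs and -0.04 for 13354 protein-coding genes, and 0.69, 0.62, 0.72, 0.45, 0.18 and -0.02 in XX-WT against XY-WT. With the GC and length trend removed, these medians were 0.97, 0.77, 0.79, 0.68, 0.43 and 0.02 in XY-KO. In XX-WT they were then 0.63, 0.25, 0.29, 0.40, 0.21 and 0.03. Few genes of the first 5 types were called in XY-KO (1, 2, 0, 0 and 7 higher and none lower). No test of a type was run.

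Of the tests that follow, those of shared sampling error, of position and covariance after trend removal, of position over genes chosen on XY-KO against XX-WT, of Sertoli position, of the ovary-biased slope, of a common fall, of the Sertoli list after trend removal and of the slope between XY-KO and XX-WT were chosen after the result was seen; the other 2 were written down before theirs.

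Sex-biased genes stood part of the way from XY-WT to XX-WT in XY-KO. Sampling error of the shared XY-WT libraries, if independent between genes, is argued against as the whole source by the covariance of the 2 changes. This covariance exceeded the simulated shared error by 0.162 (jackknife SE 0.0101 over 22 chromosomes). The jackknife SEs here measure the spread between chromosomes, not between libraries. XY-WT error common to many genes is therefore not covered. Yet the median position over genes chosen on XY-KO against XX-WT, -0.0263, lay within the range simulated with XY-KO unchanged (highest draw -0.0236). Among genes called in that comparison with no fold limit, XY-KO lay between the controls for 43.4%. This was above the 37.6 to 41.7% simulated with XY-KO unchanged. The GC and length trend as the whole source is argued against by the median position after its removal, 0.152 against 0.0364 simulated with XY-KO unchanged; over genes at or above median expression it was 0.0874 (SE 0.0138) against 0.0157, and the covariance above shared error was 0.0480 (jackknife SE 0.00400) there. Lower expression of Sertoli cell genes is argued against for the ovary-biased genes as a set only if errors are independent between genes, as in the draws. The slope of the ovary-biased genes with sampling error taken out was 0.160 (jackknife SE 0.0186), against 0.0381 simulated with XY-KO unchanged (highest draw 0.0593). XY-WT error common to many genes could give such a slope too. That slope was not computed with the GC and length trend removed, where the median position of these genes was 0.211. The ovarian somatic and meiotic lists lay at 0.0557 and 0.0119, or 0.0811 and 0.0107 with the trend removed, so the slope does not speak for them. For testis-biased genes, lower expression of Sertoli cell genes stays open. The 25 testis-biased Sertoli list genes stood only 0.0112 above 935 other testis-biased genes (0.193 against 0.182, permutation p 0.880). A difference of the XY-WT libraries other than GC and length also stays open, since the controls could not be split.

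Sertoli cell markers were lower as a list in XY-KO. Fewer Sertoli cells at unchanged expression per cell would lower all markers alike, but the changes of the 25 testis-biased markers differed beyond their errors (heterogeneity chi-square 377.8, or 339.7 with the trend removed, on 24 degrees of freedom around a common change of -0.93); markers share libraries, and with 1 error shared by all of them p was 0.00141 and 0.00214. For 4 of them, Inhbb, Rhox8, Hsd17b3 and Vnn1, the 95% interval reached 0. GC content and length as the source of the fall are argued against by the list median after trend removal, -0.83, with 14 markers still called lower. It may be that markers depend on SOX9 to different degrees, which is a hypothesis found on these data; expression of a marker in other cells was not tested and stays open.

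Fold changes against XY-WT fell with GC content in both XY-KO and XX-WT. A limited set of GC-rich testis genes is argued against, as 84.1% of the 953 genes in the highest GC eighth lay below 0 in XY-KO and 73.6% in XX-WT. A library or RNA quality difference between XY-WT and the other samples cannot be told apart from a tissue difference: the slope between XY-KO and XX-WT was -0.00148 per 10 points, but XY-WT is also a group of the design. Unspliced or genomic sequence cannot be told apart either. Among protein-coding genes, the correlation with length in the 2565 of lowest expression minus that in the 7408 highest was -0.117 (SE 0.0229). A lower correlation among the low genes was the outcome set beforehand as going against this source. Yet larger errors among the low genes (median SE 0.404 against 0.153) shrink a correlation. The slopes on log2 length, compared after that result was seen, were 0.0591 (SE 0.0158) and 0.0787 (SE 0.00386), a difference within 2 SE. The gene type medians given above were not part of the length test. Biological causes in the testis were not tested.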
